A study of Mus musculus with 18 samples.

How the data were processed

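Ribosome-protected fragments (RPF) and mRNA were measured in 18 libraries of mouse fibroblasts of the NIH3T3 line, with 3 libraries per group and assay. The groups were WT cells, cells edited at Mtor to carry C1483Y (G4448A in the coding sequence), and WT cells given Torin1 at 200 nM for 3 h. Per the labels' protocols, RPF were released with RNase I, mRNA was fragmented by heat, both were size-selected on gels, and libraries were made with a small-RNA kit and sequenced on a HiSeq 2000. No molecular identifiers are mentioned there, so PCR copies count as separate reads, and intervals and floors cover counting error alone.

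Each of the authors' deposited files gives whole-number counts of reads per gene for 1 library, with no normalization. Per the submitters' processing notes, the tools named for these libraries are Bowtie 1.1.2, TopHat2 2.1.1 and HTSeq, with the mouse build mm10; their order and settings are not given in the sources used here. The files hold 24035 genes by symbol, of which 23894 matched a RefSeq symbol of the same build (GRCm38.p6). Another 27 lines carry calendar dates in place of gene symbols, with 2 dates appearing more than once per file; these took 0.089% to 0.264% of gene counts and were left out, so genes of the septin and March families under their older symbols were not analysed here. The 5 summary lines of the counting were also left out of library sizes and tests. Of these, reads aligned to more than 1 place made up 22.2% to 47.5% of all counted lines in RPF libraries and 49.3% to 95.9% in mRNA libraries. Reads outside annotated genes were 4.28% to 27.0% of gene plus unassigned reads in RPF libraries and 17.3% to 34.4% in mRNA libraries, and ambiguous reads 0.04% to 0.9% of all counted lines. Totals of reads too low in quality and of unaligned reads were listed at 0. Reads placed at more than 1 site did not enter gene counts, so ribosomal protein genes, Eef1a1, Gapdh, histones, Hspa1l, Pbp2 and other genes with near-identical copies or pseudogenes are uncertain in level.

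Counts were tested with edgeR 4.0.16 (quasi-likelihood test on group means, TMM factors and the filterByExpr filter within each assay) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The RPF and mRNA comparisons each used all 9 libraries of the assay, so that 3 groups shared an estimate of the spread. Translational efficiency (TE), the RPF level of a gene relative to its mRNA level, was tested as the interaction of assay and cells in a model over all 18 libraries, for genes that passed the filter in both assays. There were 7 comparisons: C1483Y against WT and Torin1 against WT for RPF, mRNA and TE, and C1483Y against Torin1 for TE. The spread between libraries was wide: the median biological coefficient of variation was 0.9 in RPF, 2.19 in mRNA and 1.62 in the TE model. CPM values follow TMM scaling and are given as mean ± SD over 3 libraries. A fold against a group with 0 reads was computed against a floor of 3 reads summed over that group and is a lower bound, and with 1 to 3 reads the ratio is given with a counting interval at 95% confidence. In a single library 3 reads are 0.07 to 0.641 ppm of gene counts in RPF and 0.032 to 0.679 in mRNA, before TMM scaling. Shares of reads in a library have Wilson intervals at the same level.

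The comparisons, 25 gene lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. The lists were: ribosomal proteins, other TOP mRNAs (transcripts that begin with a terminal oligopyrimidine tract), mitochondrial ribosomal proteins, the nuclear-encoded respiratory chain, the proteasome, ribosome biogenesis, amino acid response (Atf4) genes, cytosolic aminoacyl-tRNA synthetases, cholesterol and fatty acid synthesis (Srebp) genes, glycolysis and hypoxia (Hif1a) genes, lysosome and autophagy (Tfeb) genes, Foxo target genes, mTOR pathway genes, cap-dependent translation initiation factors, cell cycle genes, serum response and immediate early genes, extracellular matrix and fibroblast genes, interferon-stimulated genes, protein folding and unfolded protein response, replication-dependent histones, and markers of adipocytes, muscle, epithelia, leukocytes with endothelium, and neurons with glia. Lists with at least 5 measured genes were tested with camera from limma 3.58.1 at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison, and again with a correlation estimated per list and with fry. The 5 marker lists had fewer than 5 genes past the filter in each assay, as had interferon-stimulated genes in mRNA, and were not tested; marker values are given per library.

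The rule for named genes took genes past the threshold with a mean of at least 10 CPM: the 10 with the largest rise and the 10 with the largest fall in RPF and TE against WT, and 5 each way for mRNA and for C1483Y against Torin1. Where none passed in a direction, the 3 with the smallest p were taken and are said not to pass. For each list that passed, up to 4 members with the smallest p were added, and 12 genes were followed in every comparison (Mtor, Adk, Rps6, Eef2, Eef1a1, Pabpc1, Eif4ebp1, Atf4, Sqstm1, Hif1a, Ccnd1 and Srebf1). Some genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

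The alternatives were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, the 2 compared groups alone, a replicate block, TMM factors over all 18 libraries, a fold of at least 1.5, and leaving out each replicate in turn. Leaving out 2 near-identical mRNA libraries was added after seeing the data. Pseudocount alternatives, planned for normalized values, were not needed for counts. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

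The tests were tested on simulated data with the real library sizes and the WT means in every group. Each gene kept its spread from the fit over all groups. At each of 4 fold sizes, 50 genes drawn at random over all expression levels were changed. The shares called therefore do not describe abundant genes with a small spread. In the real Torin1 RPF data, P4hb and Ldha were called at falls of less than 4-fold. For Torin1 RPF the test called 0% of genes changed 2-fold or 4-fold, 46% of those changed 16-fold and 70% of those changed 256-fold, with 0.02% of unchanged genes called. For Torin1 mRNA it called 0% at 2-fold, 4-fold and 16-fold and 16% at 256-fold, with 0% of unchanged genes called. For Torin1 TE it called 0% up to 16-fold and 26% at 256-fold, with 0.016% of unchanged genes called.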

Results

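Ribosome profiling and mRNA sequencing were used to compare the transcriptome and the translated mRNA of 3 kinds of NIH3T3 cells, an established line of mouse fibroblasts: WT cells, cells edited at Mtor to encode C1483Y, and WT cells given Torin1, an ATP-competitive inhibitor of the mTOR kinase, at 200 nM for 3 h. Ribosome profiling sequences the mRNA stretches that ribosomes shield from nuclease. Mtor encodes the kinase at the centre of the nutrient-sensing mTOR complexes, and lies on chromosome 4 from 148448582 to 148557685 (GRCm38). Each group had 3 RPF and 3 mRNA libraries. Gene counts, in M reads, in replicates 1, 2 and 3 of the RPF libraries were 13.28, 42.82 and 13.04 M for WT, 4.68, 4.69 and 6.96 M for C1483Y, and 16.8, 19.95 and 31.07 M for Torin1. In the mRNA libraries they were 26.69, 94.3 and 56.34 M for WT, 4.42, 42.29 and 5.7 M for C1483Y, and 12.06, 51.74 and 38.34 M for Torin1. The labels do not say that replicates were separate cultures, so p-values of single genes measure the spread between these libraries, which may be technical. A single edited line was labelled, so the edit and the line could not be separated.

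Mtor itself had 425, 2328 and 209 RPF reads in the WT libraries, 762, 1384 and 696 in the libraries labelled C1483Y, and 619, 820 and 1539 in the Torin1 libraries. In mRNA it had 0 reads in all 3 WT libraries, 135, 0 and 1 in the libraries labelled C1483Y, and 0, 285 and 0 in the Torin1 libraries, so it was not tested there. Counts per gene do not show the edited base. Tmem38b, which encodes an intracellular cation channel and was chosen after its values were seen, took between 0.04% and 37.0% of the gene counts of single RPF libraries, with wide differences between replicates in all 3 groups, and at most 0.05% in mRNA libraries.

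Most mRNA libraries detected fewer genes than any RPF library, with ranges of 5247 to 7898 and 7362 to 12430 that overlapped. With every library thinned to 4.42 M gene reads, mRNA libraries detected at most 6964 genes and RPF libraries at least 7340. Among the 7511 genes with at least 500 reads in a WT mRNA library, 2737 (36.4%) had 0 reads in another WT mRNA library, against 1.56% of 7295 such genes in WT RPF.

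**Figure D1:**
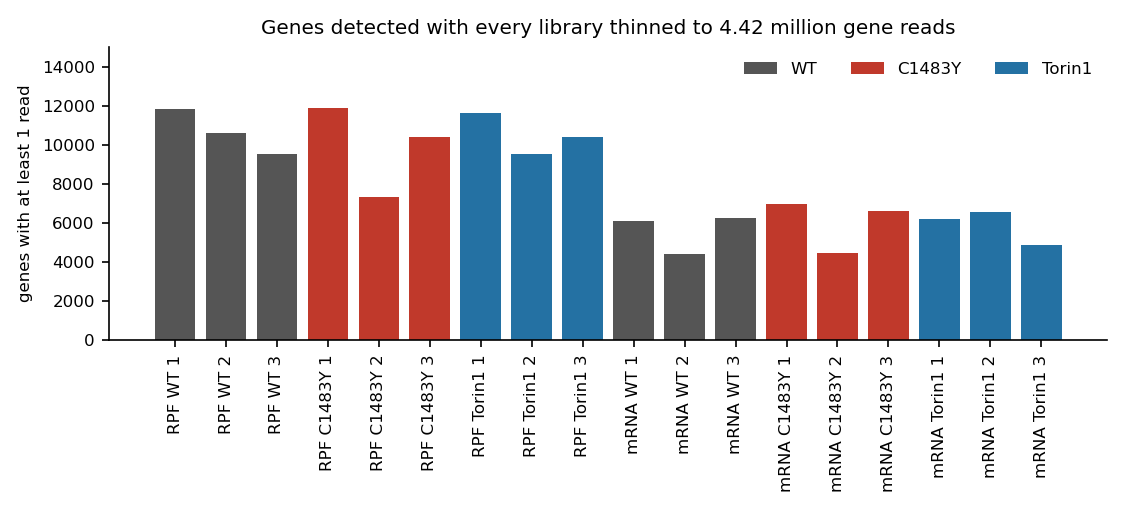
Genes with at least 1 read in each of the 18 libraries after thinning to 4.42 M gene reads; each bar is 1 library, coloured by group. The 9 mRNA libraries detected 4420 to 6964 genes and the 9 RPF libraries 7340 to 11895.

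The mRNA libraries of C1483Y replicate 2 and Torin1 replicate 3 were nearly identical despite their different labels. Their chi-square per degree of freedom was 13.0, above sampling noise but far below the 732 to 8250 of every other pair of mRNA libraries. Across genes their log2 CPM correlated with r = 0.999, against at most 0.698 for other mRNA pairs; genes are not independent replicates. Of the 2346 genes detected in only 1 of these 2 libraries, none had more than 14 reads. Both libraries stayed in the comparisons under their labels, and counts without them are given where they differ.

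**Figure D2:**
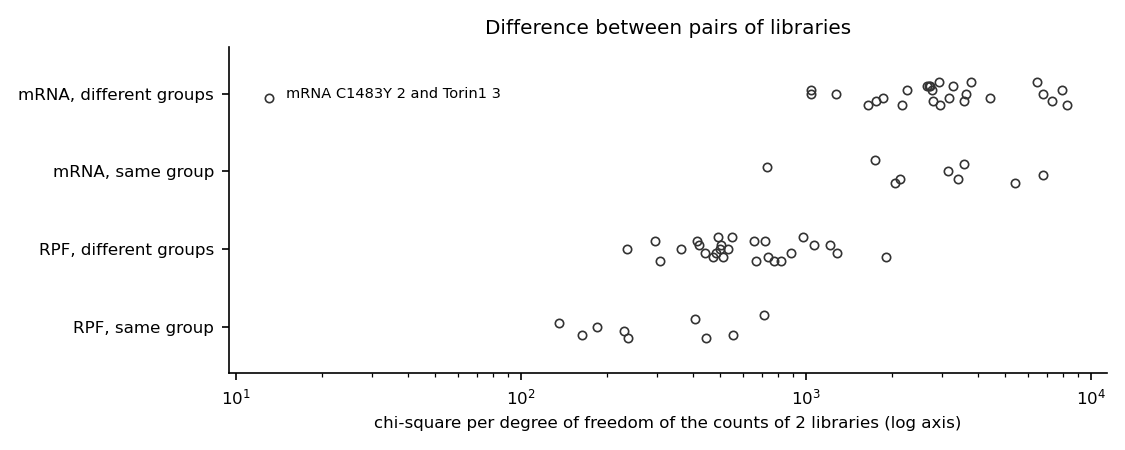
Chi-square per degree of freedom (log axis) between the counts of every 2 libraries of an assay, by whether they share a group; each circle is a pair. The pair of mRNA C1483Y replicate 2 and mRNA Torin1 replicate 3 lies at 13.0, and the other mRNA pairs at 732 or above.

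Libraries labelled C1483Y also stood apart in what their reads matched. Reads on 358 genes that RefSeq classes as pseudogenes made up 7091, 8642 and 4837 ppm of gene counts in the 3 RPF libraries labelled C1483Y (widest 95% Wilson interval 8559 to 8726), against 588 to 1472 in the WT and Torin1 RPF libraries. In mRNA the values were 12322, 1040 and 7596 ppm in C1483Y replicates 1, 2 and 3, and 1050 to 2125 in the WT and Torin1 libraries. Col1a1, a collagen that fibroblasts secrete, chosen here after its values were seen, stood at 16.4 to 135 CPM in RPF labelled C1483Y and at 2580 to 5320 CPM in WT RPF; in mRNA it stood at 17.8, 1140 and 13.2 CPM in C1483Y replicates 1, 2 and 3, and at 855 to 3230 CPM in WT.

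**Figure D3:**
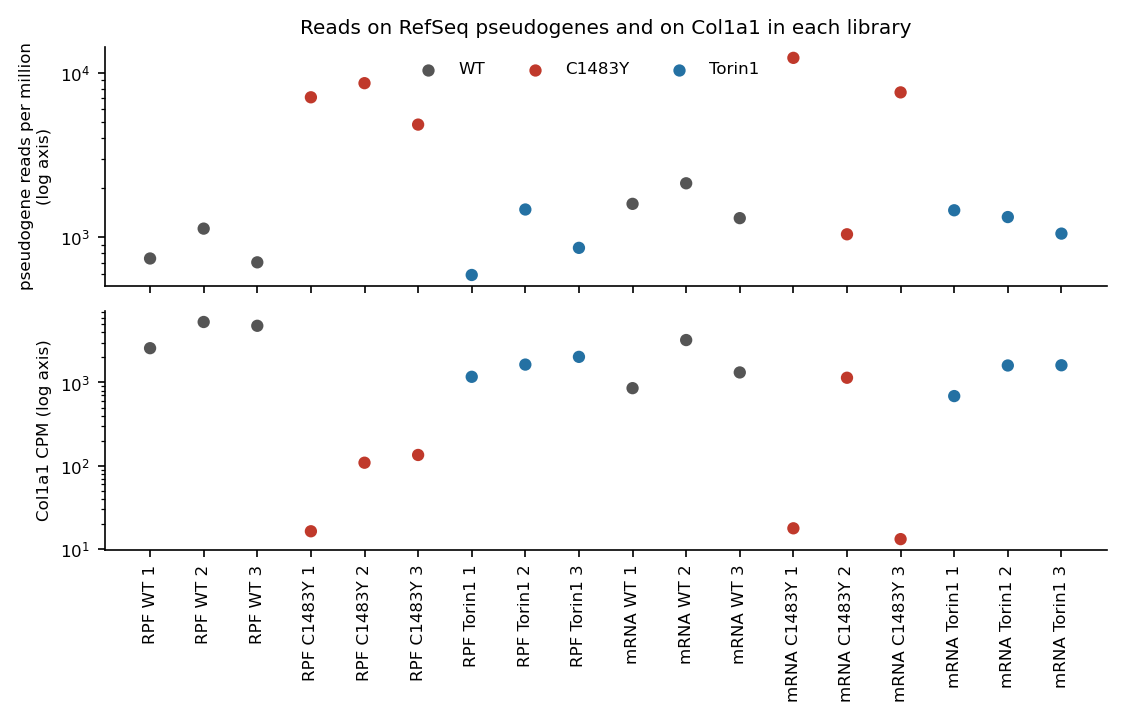
Reads on RefSeq pseudogenes in ppm of gene counts (top, log axis) and Col1a1 CPM (bottom, log axis) in each library; each point is 1 library, coloured by group. RPF labelled C1483Y held 4837 to 8642 ppm of pseudogene reads, against 588 to 1472 in the other RPF libraries.

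The first question was which mRNAs lost or gained ribosomes relative to other mRNAs when mTOR was inhibited. Counts were scaled within each assay, so a loss or gain of ribosomes shared by all mRNAs would not show. A gene that was not called may still have lost ribosomes. Torin1 lowered RPF counts of the translation machinery. Eef1a1 (chromosome 9, 78478453 to 78481724), which delivers aminoacyl-tRNA to the ribosome, fell from 7520 ± 830 CPM in WT to 943 ± 33 CPM (SD, n = 3; log2 fold change -3.00 ± 0.21, SE, adjusted p = 0.000163). Eef2 (chromosome 10, 81176631 to 81182509), which moves the ribosome along the mRNA, fell from 5350 ± 1450 to 960 ± 110 CPM (log2 -2.48 ± 0.24, adjusted p = 0.00126). Rps6, a ribosomal protein that mTOR signalling phosphorylates, fell from 3520 ± 399 to 797 ± 101 CPM (log2 -2.14 ± 0.23, adjusted p = 0.00126). The poly(A)-binding protein gene Pabpc1 (log2 -2.68 ± 0.29), the growth-related gene Tpt1 (-2.90 ± 0.26), the elongation factor subunit gene Eef1b2 (-2.80 ± 0.42) and Rps19 (-3.01 ± 0.36) also fell, with adjusted p from 0.00081 to 0.00748.

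Among lists, 59 of 79 ribosomal protein genes fell and 0 rose (75 fell adjusted over the list alone). The median log2 change was -1.97, with library medians of -1.86, -2.13 and -1.89 against the WT mean. At the preset correlation of 0.01 camera gave adjusted p = 3.96e-212. That setting treats the genes of a list as nearly independent, so such a small p-value does not measure the spread between libraries. Rps18 (log2 -2.58 ± 0.22) and Rpl8 (-2.36 ± 0.24) were among those with the smallest p-values, and Rpl37, Rpl31, Rpl27a and Rpsa also fell (-2.64 to -2.49). Of 31 other TOP mRNAs, 11 fell (24 adjusted over the list alone, median -1.04, adjusted p = 5.39e-55). With DESeq2 size factors the medians were -1.90 and -0.97. Both calls held with an estimated correlation, as did those of 7 more lists that were lower than other genes. These were amino acid response genes (median -1.05; 1 of 36 fell, 6 adjusted over the list alone), Srebp genes (-0.80; 0 of 35), the respiratory chain (-0.57; 0 of 74), protein folding genes (-0.55; 2 of 29 fell, 4 adjusted over the list alone), the proteasome (-0.44; 0 of 36), initiation factors (-0.41; 2 of 36 fell, 6 adjusted over the list alone) and tRNA synthetases (-0.41; 0 of 20), with the 0 counts the same adjusted over the list alone. Their adjusted p with an estimated correlation ranged from 0.00502 to 0.0492.

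Single members of these lists that fell included the leucine transporter gene Slc7a5 (log2 -1.64 ± 0.32, adjusted p = 0.0427), the chaperone gene Hspa8 (-2.03 ± 0.22, adjusted p = 0.00142), P4hb (-1.21 ± 0.23, adjusted p = 0.0316), and the initiation factor subunits Eif3f (-1.94 ± 0.32, adjusted p = 0.016) and Eif3h (-1.39 ± 0.28, adjusted p = 0.0487). The serine synthesis gene Psat1 (log2 -1.63, adjusted p = 0.0594), the mTOR inhibitor gene Ddit4 (-2.86, adjusted p = 0.0793), the fatty acid synthase gene Fasn (-1.17, adjusted p = 0.147) and the ATP synthase gene Atp5g2 (-1.85, adjusted p = 0.16) did not pass.

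For 6 lists the camera call was lost with an estimated correlation. Glycolysis genes had a median of -0.41, with 2 of 27 down (7 adjusted over the list alone, adjusted p = 0.0949 with an estimated correlation); Gapdh (-2.05) and Ldha (-1.20) fell. The medians of the others, with 0 genes called in each over all genes or over the list alone, were -0.37 for mitochondrial ribosomal proteins (adjusted p = 0.386 with an estimated correlation), -0.28 for ribosome biogenesis (adjusted p = 0.0516), -0.20 for cell cycle genes (adjusted p = 0.0907, and 0.0553 at the preset correlation with DESeq2 size factors), 0.68 for Foxo targets (adjusted p = 0.129) and 0.72 for immediate early genes (adjusted p = 0.145). Cited2 (0.95) and Jun (0.80), members of the last 2 lists, had adjusted p = 1. The other 5 lists did not pass: extracellular matrix genes (median -0.27; 1 of 41 fell, 3 adjusted over the list alone), interferon-stimulated genes (0.14; 13 measured), lysosome genes (-0.14; 47 measured), mTOR pathway genes (0.18; 44 measured, 1 fell adjusted over the list alone) and histones (-0.03, or 0.03 with DESeq2 size factors; 59 measured).

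**Figure D4:**
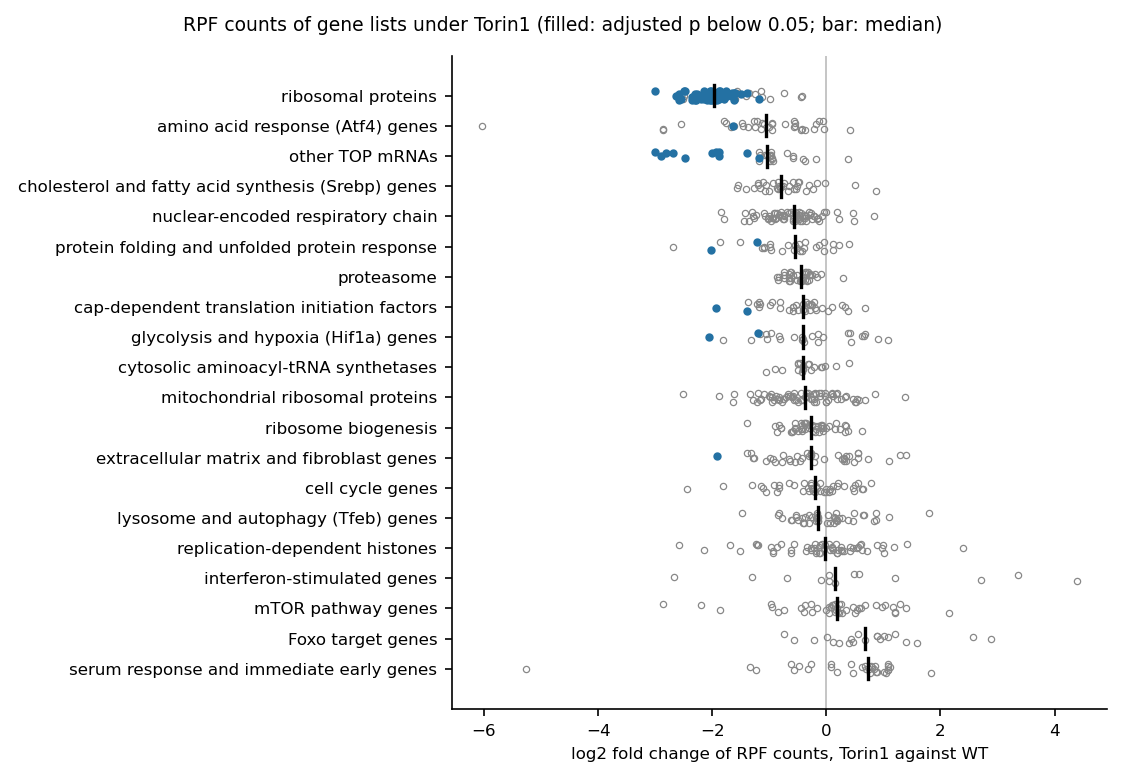
Log2 fold change of RPF counts, Torin1 against WT, for every tested gene of the 20 lists; each point is a gene, filled where its adjusted p was under 0.05, and the bar is the list's median. Ribosomal proteins have the lowest median, -1.97, and 59 of their 79 genes are filled.

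In all, edgeR called 82 of 11085 genes lower and 1 higher under Torin1, and 460 genes had an unadjusted p under 0.05. The gene that rose was Foxred2 (chromosome 15, 77940522 to 77958503), with 14, 96 and 165 reads in the Torin1 libraries and 1 read over the WT libraries, a ratio of 268 (95% counting interval 47.7 to 10600, adjusted p = 0.0168); it stood at 120 ± 38.2 CPM in RPF labelled C1483Y. It kept its call in 6 of 12 alternatives, while Eef1a1, Eef2, Pabpc1, Tpt1, Rps6, Rps18, Rps19 and Hspa8 kept theirs in all 12. Of the other genes named as lower, Eif3h kept its call in 3 of 12, Slc7a5, P4hb and Ldha in 5, Eif3f in 6, Rpl31 in 7, Rpl27a in 8, Gapdh in 9 and Eef1b2 in 11, and Rpl8, Rpl37 and Rpsa in all 12. Mtor (log2 0.25 ± 0.48), Adk (-0.10), Sqstm1 (0.17), Hif1a (0.38), Ccnd1 (-0.66), Srebf1 (0.51), Atf4 (-1.22) and Eif4ebp1 (-0.97) all had adjusted p = 1. The count of 83 fell to 33 without WT replicate 1, 53 without WT replicate 3, and 39, 47 and 40 without Torin1 replicates 1, 2 and 3. It was 138 with the 2 groups alone (9 higher and 129 lower), 209 by DESeq2 (26 and 183) and 206 by limma-voom (19 and 187).

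The mRNA levels of the same genes were compared to see whether transcript abundance moved as well. Eef1a1 mRNA was at 12900 ± 4350 CPM under Torin1 and 10500 ± 4060 CPM in WT (log2 0.30 ± 0.30, adjusted p = 1), Eef2 at 7750 ± 2190 and 4610 ± 523 CPM (0.75 ± 0.42, adjusted p = 0.778), and Rps6 at 3890 ± 434 and 4010 ± 854 CPM (-0.05 ± 0.55, adjusted p = 1). The median log2 change was -0.05 over 80 ribosomal protein genes and 0.20 over 30 other TOP mRNAs, and 0 of 19 lists passed by camera (smallest adjusted p = 0.554). In 3 of them the test, the median and the mean differed in sign. The only gene that edgeR called among 7121 was Irs4 (chromosome X, 141710998 to 141725217), an insulin receptor substrate (log2 11.44 ± 2.54, adjusted p = 0.0493). Its reads lay almost wholly in Torin1 replicate 3, the near-identical library, with 16208 reads, against 0 and 4 in replicates 1 and 2. Without that library the log2 change was -0.46 and 0 genes were called. Ckb, Tuba4a and Tmem115 had the smallest p-values among lower genes and did not pass (adjusted p from 0.457 to 0.652). Most of their WT reads lay in WT replicate 2: Ckb had 3, 692 and 2 reads in WT replicates 1, 2 and 3 and 0, 1 and 2 under Torin1, Tuba4a 5554, 54591 and 4455 against 3, 5 and 0, and Tmem115 13, 45067 and 2194 against 5, 0 and 0. No gene was called lower by edgeR, with 507 genes in either direction at an unadjusted p under 0.05; DESeq2 called 194 lower and 330 higher, and limma-voom 7 lower and 9 higher. The count was also 0 without Torin1 replicate 2 and without each of WT replicates 1, 2 and 3.

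**Figure D5:**
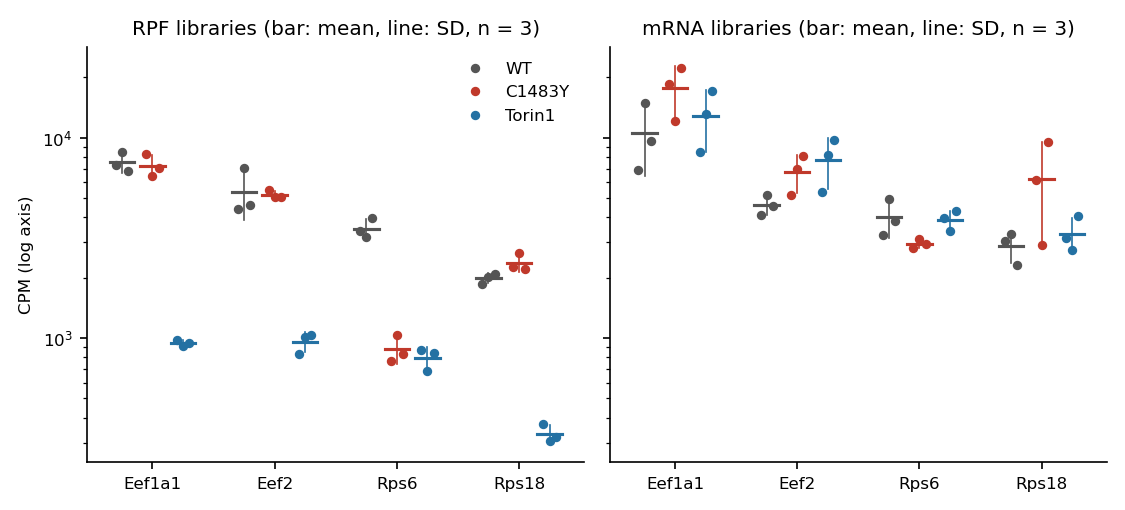
CPM (log axis) of Eef1a1, Eef2, Rps6 and Rps18 in RPF (left) and mRNA (right) libraries; points are libraries, bars the mean and lines the SD of 3. In RPF the Torin1 libraries lie below every WT library for all 4 genes, as for Eef1a1 at 907 to 972 against 6850 to 8450 CPM.

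Translational efficiency combines these measurements. Under Torin1 the TE of Eef1a1 fell by 3.23 on the log2 scale (SE 0.46, adjusted p = 0.000533) and that of Eef2 by 3.16 (SE 0.51, adjusted p = 0.00203), and these were the only genes edgeR called among 7072. Ribosomal protein genes had a median TE change of -1.85, with 78 of 79 below 0 and 0 called (18 fell adjusted over the list alone, camera adjusted p = 1.77e-14). Other TOP mRNAs had a median of -1.27, with 2 of 30 down (9 adjusted over the list alone, adjusted p = 0.000216). With DESeq2 size factors these medians were -1.80 and -1.29. Both lists had adjusted p = 0.23 with an estimated correlation and 0.0011 by fry. Rps18 (-2.72), Rps19 (-3.37), Rpsa (-2.72) and Rps4x (-2.47) among ribosomal proteins and Gnb2l1 (-2.40) and Eef1g (-2.37) among TOP mRNAs did not pass alone (adjusted p from 0.172 to 0.225), nor did Rps6 (-2.04, adjusted p = 0.225) or Pabpc1 (-2.03, adjusted p = 0.764). No gene was called higher; Anp32b, Tuba4a and Cetn2 had the smallest p-values (adjusted p from 0.172 to 0.225). DESeq2 called 214 higher and 368 lower, limma-voom 0 and 17, and 782 genes had an unadjusted p under 0.05 in edgeR. Eef1a1 and Eef2 kept their calls in 13 of 15 alternatives, the exceptions being DESeq2 size factors and TMM factors over all 18 libraries, with 0 genes called in each. Without the 2 near-identical mRNA libraries 44 genes were called, 41 of them lower. The other 17 lists did not pass, and in 5 of them the test, the median and the mean differed in sign.

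The libraries labelled C1483Y were then compared with WT. Their differences cannot be assigned to the Mtor substitution, for reasons given among the flagged results. Cdkn2a, which the NIH3T3 line has lost, was chosen after its values were seen. It had 467 to 1447 reads in RPF labelled C1483Y and 0 to 4 in WT RPF. RPF of the libraries labelled C1483Y differed from WT in 2060 of 11085 genes, 877 higher and 1183 lower. Among lists that passed, secreted and matrix genes of fibroblasts had the lowest median: 36 of 41 extracellular matrix genes fell and 0 rose (38 fell adjusted over the list alone), with a median log2 change of -4.41 (camera adjusted p = 1.29e-30, and adjusted p = 0.12 with an estimated correlation). Sparc, a matrix glycoprotein, fell from 932 ± 216 CPM in WT to 18.6 ± 12.4 CPM (SD, n = 3; log2 -5.65 ± 0.51, SE, adjusted p = 0.000107), the matrix protease Mmp14 from 387 ± 74.8 to 8.54 ± 2.38 CPM (-5.50 ± 0.38), and the collagen Col5a2 (-6.34) and the protease inhibitor Timp1 (-4.41) fell too. The libraries concerned are those with 4837 to 8642 ppm of pseudogene reads.

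Genes at 0 or 1 read in WT were abundant in the same libraries. Uchl1, a deubiquitinase of neurons, had 5793 reads against 1 in WT (ratio 30200, 95% counting interval 5410 to 1190000). Lower bounds, against 0 WT reads, were at least 5860-fold for the chaperone Hspa1l, 4470-fold for carbonic anhydrase Car2, 4300-fold for Coch, 4070-fold for the fibrillin Fbn2, 3720-fold for the kinesin Kif1a, 3110-fold for the homeobox gene Hoxd13, 3010-fold for Pbp2, 2910-fold for Kctd12 and 2700-fold for Chchd10. In the other direction, 0 reads were left of Pear1 (at least 292-fold lower), Pcdhgb2 (208-fold), Lrrk1 (197-fold), the transcription factor Ebf1 (171-fold), Rhod (168-fold), Tnfaip6 (149-fold), Map6 (140-fold), Haus7 (135-fold) and Gm14005 (126-fold). Each of these genes had adjusted p under the threshold. Tgm2 also had 0 reads left, but its WT reads were 223, 2805 and 0 in replicates 1, 2 and 3, and its call (adjusted p = 0.0429) was kept in only 4 of 11 alternatives.

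Further lists passed in camera, and with an estimated correlation none of these calls held, matrix genes included (adjusted p = 0.12). Srebp genes had 16 of 35 down and 1 up (20 and 2 adjusted over the list alone, median -2.36, adjusted p = 0.151 with an estimated correlation), among them Scd2 (-3.49), Fdps (-3.46) and Msmo1 (-4.45). Of 47 lysosome genes 16 fell (18 adjusted over the list alone, median -1.22, adjusted p = 0.143 with an estimated correlation), including the cathepsins Ctsb (-5.64) and Ctsl (-4.74), Psap (-4.03) and Npc2 (-3.45). Cell cycle genes had 13 of 43 down and 2 up (17 and 3 adjusted over the list alone, median -0.81, adjusted p = 0.143), with Top2a, Ccnd1, Cdk1 and Tk1 down (-3.64 to -2.06). Immediate early genes had 8 of 32 down and 1 up (11 and 1 adjusted over the list alone, median -2.73, or -2.23 with 5 genes at their bound, adjusted p = 0.151), among them Ctgf (-4.09) and Cyr61 (-3.45), with Fosl1 at least 109-fold and Dusp5 at least 121-fold lower. Initiation factors went the other way, with 8 of 36 up and 3 down (9 and 3 adjusted over the list alone, median 0.42, adjusted p = 0.143): Eif1 (1.46), Eif4g2 (1.57), Eif1a (2.35) and Eif5a (1.30) rose. The other 14 lists did not pass, and in 3 of them the test, the median and the mean differed in sign. Ribosomal proteins, at a median of 0.09, had 17 up and 13 down of 79 (21 and 16 adjusted over the list alone) and passed as higher with DESeq2 size factors (0.17, adjusted p = 0.0431), and other TOP mRNAs, at -0.03 (0.03 with DESeq2 size factors), 6 up and 4 down of 31 (7 and 4 adjusted over the list alone).

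Mtor RPF rose from 32.6 ± 18.1 CPM in WT to 199 ± 60.8 CPM (log2 2.61 ± 0.51, adjusted p = 0.00494). Rps6 (-2.00), Adk (-1.81), the autophagy receptor gene Sqstm1 (-2.55), the cyclin gene Ccnd1 (-3.64) and Srebf1 (-3.90, adjusted p = 0.0379, kept in 7 of 12 alternatives) fell, while Eef1a1 (-0.06 ± 0.20, adjusted p = 0.878), Eef2 (-0.04 ± 0.23, adjusted p = 0.926), Pabpc1 (-0.06), Atf4 (0.56), Eif4ebp1 (1.38, adjusted p = 0.0732) and Hif1a (-1.05, adjusted p = 0.0661) did not pass. Markers of other cell types were summed per library. A sum can rest on 1 member of a list and does not by itself show a cell type. Muscle markers came to 3120, 3900 and 1960 CPM in RPF labelled C1483Y against 7.29 to 44.3 CPM in WT, neuronal and glial markers to 1190, 923 and 1180 against 15.6 to 22.7 CPM, and epithelial markers to 53.8, 113 and 27.5 against 0.0716 to 0.439 CPM. Adipocyte markers came to 22.3, 0 and 22.6 CPM against 32.9 to 84.6, and leukocyte and endothelial markers to 2.51, 0 and 17.2 CPM against 3.37 to 22.4. The count of 2060 was 1255, 1163 and 1307 without WT replicates 1, 2 and 3, 3161 without C1483Y replicate 2, and 3693 by DESeq2. With the 2 groups alone it was 1522, and more genes were higher (802) than lower (720).

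In mRNA, C1483Y replicate 2 stood apart from replicates 1 and 3. Reads and CPM are given by replicate, while log2 changes, ratios of sums and list medians pool these unlike libraries. Chi-square per degree of freedom was 732 between replicates 1 and 3, the lowest of mRNA pairs but the near-identical one. Against replicate 2 it was 3160 and 3580. Log2 CPM correlated with r = 0.595 between replicates 1 and 3, and 0.479 and 0.464 against replicate 2. Matrix genes summed to 2010, 26200 and 3740 CPM in replicates 1, 2 and 3, against 17100 to 40400 CPM in WT, and muscle markers to 3910, 0.31 and 2580 CPM; replicate 2 is the near-identical library. Of 7121 genes 23 rose and 0 fell by edgeR. Irs4 stood at 458, 355 and 1200 CPM against at most 0.143 in WT (log2 13.40 ± 2.71, adjusted p = 0.000461). The histone gene Hist2h2be had 16198, 2 and 2204 reads against 8, 14 and 3 in WT (adjusted p = 1.14e-08). The transcription factor Foxo3 had 1208, 0 and 5158 reads against 3 over the WT libraries (ratio of sums 6270, 95% counting interval 2140 to 30400). Dpcd had 2609, 2714 and 1884 against 3 (7100, interval 2430 to 34400). These intervals cover counting error alone, while 36.4% of genes with at least 500 reads in a WT mRNA library had 0 in another. Foxo3 stood at 7.02 to 19.0 CPM in WT RPF and 67.8 to 283 CPM in RPF labelled C1483Y. Dpcd stood at 6.83 to 23.4 and 27.6 to 58.0 CPM there. Under Torin1, Dpcd had 1573, 2 and 2304 mRNA reads. The few WT mRNA reads of Foxo3 and Dpcd thus do not show absence, and the size of their rise stays uncertain. Calls were kept in 9 of 13 alternatives for Hist2h2be, 8 of 13 for Irs4, 4 of 13 for Dpcd and 3 of 12 for Foxo3. Lgals1 (log2 -1.86), Actb (-1.43) and Ftl1 (-2.10) led the lower genes and did not pass (adjusted p from 0.0798 to 0.107). These pooled changes hide the difference between replicates. Actb stood at 1645, 7891 and 1173 CPM in C1483Y replicates 1, 2 and 3, and at 5938 to 15760 CPM in WT.

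The 4 lists that passed in camera for mRNA were matrix genes (median -1.37), Srebp genes (-1.60), mitochondrial ribosomal proteins (-1.43) and the respiratory chain (-0.84), all with 0 genes called over all genes or over the list alone and adjusted p = 0.613 with an estimated correlation. In 6 of the other 15 lists the test, the median and the mean differed in sign. DESeq2 size factors moved the median log2 change of all genes from -0.50 to 0.985 and left 0 genes called; the medians of these 4 lists stayed below 0, with the respiratory chain no longer past the threshold (adjusted p = 0.153), while ribosomal proteins (2.31, adjusted p = 0.000234), other TOP mRNAs (3.30, adjusted p = 0.00034) and initiation factors (2.91, adjusted p = 0.00308) passed as higher than other genes. At an unadjusted p under 0.05 there were 621 genes; DESeq2 called 710 higher and 105 lower, and limma-voom 1 each way. The count of 23 became 14 without WT replicate 1 or 3 and 7 without C1483Y replicate 1. It became 172 without C1483Y replicate 2 (95 higher and 77 lower). Without both near-identical libraries it was 145 (86 higher and 59 lower).

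No TE change between the libraries labelled C1483Y and WT passed in edgeR among 7072 genes; the smallest adjusted p was 0.167, and 950 genes had an unadjusted p under 0.05. Uqcrh (log2 8.70) and Capzb (8.34) were among the higher genes with the smallest p-values. Lrrc41 (-12.60), Lmbrd1 (-11.75) and Erdr1 led the lower genes, and each had adjusted p = 0.167. These changes rest on low mRNA counts in 1 of the compared groups. C1483Y mRNA replicates 1, 2 and 3 held 3, 22 and 12 Uqcrh reads and 4, 179 and 1 Capzb reads. WT mRNA replicates held 3, 1 and 1 Lrrc41 reads, 1, 7 and 8 Lmbrd1 reads, and 0, 0 and 3 Erdr1 reads. Matrix genes had a median TE change of -2.75 (0 of 38 called, 7 fell adjusted over the list alone, camera adjusted p = 0.000892) and the respiratory chain of 0.46 (0 of 72 called, 1 rose adjusted over the list alone, adjusted p = 0.0414), each with adjusted p = 0.66 with an estimated correlation; with DESeq2 size factors matrix genes stood at -3.80 and passed (adjusted p = 0.000108), and the respiratory chain stood at -0.86 and did not (adjusted p = 0.186). Collagen Col1a2 (-4.14) and fibulin Fbln2 (-4.25) were members with small p-values that did not pass. Ribosomal proteins had a median of 0.34 and did not pass, with -2.05 under DESeq2 size factors and -0.13 without WT replicate 2, and other TOP mRNAs had a median of -0.45 and did not pass. With size factors other TOP mRNAs passed in camera as lower than other genes (-2.75, adjusted p = 0.00304), and mitochondrial ribosomal proteins as higher (-0.19, adjusted p = 0.0337). Among the 17 lists that did not pass, the test, the median and the mean differed in sign in 4. Size factors moved the median TE change of all genes from 0.19 to -1.70. DESeq2 called 186 higher and 631 lower and limma-voom 1 higher; edgeR called 21 without C1483Y replicate 2, 1 without WT replicate 1 or C1483Y replicate 3, and 242 without both near-identical mRNA libraries.

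The libraries labelled C1483Y were also set directly against Torin1, to test whether these groups differed in TE without the shared WT libraries. The near-identical mRNA libraries lie on opposite sides of this comparison. TE was higher in the libraries labelled C1483Y for Eef1a1 (log2 2.60 ± 0.46, adjusted p = 0.0116), Eef2 (2.75 ± 0.50, adjusted p = 0.0132), Rps12 (3.83 ± 0.78, adjusted p = 0.046) and Rps19 (4.15 ± 0.86, adjusted p = 0.046). Ribosomal protein genes had a median of 2.35, with 3 of 79 up (47 adjusted over the list alone, camera adjusted p = 6.72e-28, and 0.0704 with an estimated correlation). Other TOP mRNAs had a median of 0.95, with 2 of 30 up (6 adjusted over the list alone, adjusted p = 0.23 with an estimated correlation). The proteasome (median 1.09; 1 rose adjusted over the list alone, adjusted p = 0.0704 with an estimated correlation), the respiratory chain (1.01; 1 rose adjusted over the list alone, adjusted p = 0.23), mitochondrial ribosomal proteins (1.65, adjusted p = 0.314) and matrix genes (-2.54, adjusted p = 0.514) also passed in camera, with 0 genes called over all genes. In 4 of the other 13 lists the test, the median and the mean differed in sign. With DESeq2 size factors the median of all genes moved from 0.36 to -1.43, Eef1a1 stood at -0.20, and 0 genes were called. Relative to other genes, ribosomal proteins (median -0.03, camera adjusted p = 2.78e-05) and mitochondrial ribosomal proteins (-0.14, adjusted p = 0.00581) were still higher and matrix genes (-3.29, adjusted p = 2.78e-05) lower under that scaling, while the respiratory chain (-0.88, adjusted p = 0.0627), the proteasome (-1.17, adjusted p = 0.587) and other TOP mRNAs (-1.49, adjusted p = 0.662) did not pass.

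Eef1a1 kept its call in 8 of 15 alternatives, Eef2 in 7, Rps12 in 4 and Rps19 in 3. By edgeR 6 genes passed, 5 higher and 1 lower, with 556 at an unadjusted p under 0.05; the count was 0 with the 2 groups alone, with TMM factors over all 18 libraries, and without Torin1 replicate 2 or 3, 1 without C1483Y replicate 1, 39 without C1483Y replicate 2 and 74 without both near-identical mRNA libraries.

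The TE changes of C1483Y and of Torin1 against WT correlated across 7072 genes with Pearson r = 0.63 and Spearman rho = 0.55. Simulated unchanged groups sharing simulated WT libraries gave 0.49 and 0.47. All simulated libraries were drawn around the WT means with the spread of the fit over all groups. Their values are therefore not those forced by the actual WT libraries. Genes are not independent replicates. The covariance was 12.12 against 5.93 in the simulations, a difference of 6.18. Without the near-identical mRNA libraries r was 0.44 against 0.40, rho 0.35 against 0.39, the share of genes changed in the same direction 61.9% against 64.3%, and the covariance 10.98 against 4.48. For RPF, r was 0.10 and rho 0.04 against 0.48 and 0.45 in simulation, and the covariance 0.43 against 1.19, a difference of -0.75. Genes lower in both RPF comparisons numbered 21, where independent lists would share 8.75, genes higher in C1483Y and lower under Torin1 numbered 17 against 6.49, and genes higher in both 1 against 0.0791. The 3 WT libraries per assay could not be divided with 2 for each comparison, so part of any excess in the same direction may come from the shared controls.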

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

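All tests of explanations in this part were chosen after the result was seen. The summary lines of the counting, which no comparison uses, held values above the highest WT library of the assay. Reads aligned to more than 1 place made up 42.87%, 47.51% and 37.83% of all counted lines in RPF C1483Y replicates 1, 2 and 3 (highest WT 35.02%). In mRNA they made up 95.88% in C1483Y replicate 1, 90.82% in C1483Y replicate 3 and 75.14% in Torin1 replicate 1 (highest WT 66.36%). Reads outside annotated genes, as a share of these and gene reads, were 21.39%, 27.03% and 13.69% in RPF C1483Y replicates 1, 2 and 3, 12.59% in RPF Torin1 replicate 2 and 7.49% in RPF Torin1 replicate 3 (highest WT 6.86%). In mRNA they were 34.35% in C1483Y replicate 1 and 33.5% in C1483Y replicate 3 (highest WT 23.84%).

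The RPF libraries labelled C1483Y stood apart from the other RPF libraries in gene counts, pseudogene reads and marker genes. Cdkn2a (chromosome 4, 89274473 to 89294619), which the NIH3T3 line has lost, had 1447, 467 and 798 reads in them and 0 to 4 in the other RPF libraries, which argues against the base change acting alone in NIH3T3 cells. Pseudogene reads of at least 4837 ppm are what a candidate explanation, reads from another organism placed on the mouse genome, would give. Retrocopies (Pgk2, Aldoart2, Rpl10l and Pabpc2) held at least 23.974% of the reads of copy plus parent in these libraries. In the WT and Torin1 RPF libraries they held at most 0.05%. The germ cell genes Prm1, Prm2, Tnp1 and Acrv1 had 0 reads in RPF labelled C1483Y. Other mouse cell types were not measured here, so the share of retrocopy reads that they would show is unknown. Mouse cells of another type therefore stay open as an explanation. Differences between C1483Y and WT or Torin1 in RPF, mRNA and TE therefore cannot be assigned to the edit, since mRNA C1483Y replicates 1 and 3 also held 12322 and 7596 ppm of pseudogene reads and 17.973% and 23.244% of retrocopy reads (with 0 Cdkn2a reads), and replicate 2 is a near-identical library.

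The near-identical mRNA libraries, C1483Y replicate 2 and Torin1 replicate 3, had a chi-square per degree of freedom of 13.0. The lowest value among mRNA pairs of the same group was 732, which argues against separate cultures that happen to be alike. A candidate explanation is the same RNA or library under 2 labels. Which label would be right was not tested, and since the value exceeds sampling noise the libraries were not counted as 1. Markers pointed both ways. Retrocopies held at most 0.003% in the pair and in the WT and other Torin1 mRNA libraries, against 17.973% and 23.244% in C1483Y replicates 1 and 3. Irs4 had 17199 and 16208 reads in the pair, and 1489 and 6517 in C1483Y replicates 1 and 3. It had at most 9 in the WT and other Torin1 mRNA libraries.

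Most mRNA libraries detected fewer genes than any RPF library, with 5247 to 7898 against 7362 to 12430 before thinning. Thinned to the same number of reads, an mRNA library detected at most 6964 genes, fewer than any RPF library, which argues against a lower depth of the mRNA libraries. Few distinct RNA fragments amplified many times are a candidate explanation, since 36.44% of genes with at least 500 reads in a WT mRNA library had 0 reads in another WT mRNA library. No biological explanation was tested.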

How the results depend on the processing

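Leaving out the 2 near-identical mRNA libraries, and the counts of other splits, were tests chosen after the result was seen. The cause was not tested for any change below unless said. The DESeq2 Wald test called 3693 genes for RPF C1483Y (2060 in edgeR), 209 for RPF Torin1 (83), 815 for mRNA C1483Y (23), 524 for mRNA Torin1 (1), 817 for TE C1483Y (0), 582 for TE Torin1 (2) and 338 for TE C1483Y against Torin1 (6). limma-voom gave 206 for RPF Torin1, 2 and 16 for mRNA C1483Y and Torin1, 1 and 17 for TE C1483Y and Torin1, and 2 for the direct TE comparison. DESeq2 size factors in edgeR gave 0 for both mRNA comparisons, 11 for TE C1483Y, 0 for TE Torin1 and 0 for the direct comparison. Without a filter there were 14 for mRNA C1483Y, 0 for mRNA Torin1, 6 for TE C1483Y and 5 for TE Torin1. The 2 groups alone gave 138 for RPF Torin1, 2 for mRNA Torin1, 8 for TE Torin1 and 0 for the direct comparison. TMM factors over all 18 libraries gave 0 for TE Torin1 and for the direct comparison. Without the near-identical libraries there were 145 genes for mRNA C1483Y, 0 for mRNA Torin1, 242 for TE C1483Y, 44 for TE Torin1 and 74 for the direct comparison.

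Residuals of same-numbered libraries correlated at 0.01 to 0.14 in RPF, with 1 of 9 pairs over 0.1, against -0.09 to 0.01 for libraries of different numbers, and Tmem38b took its lowest share in RPF replicate 2 of each group. Whether RPF replicates share a number for a reason stays open. In mRNA the values were -0.40 to 0.27 against -0.42 to 0.67, and between assays -0.04 to 0.03 against -0.05 to 0.06. A replicate block gave 1595 genes for RPF C1483Y, 85 for RPF Torin1 and 0 for mRNA Torin1, and a replicate block by culture gave 5 for TE C1483Y, 6 for TE Torin1 and 10 for the direct comparison.

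Leaving out 1 library gave 1163 to 3161 genes for RPF C1483Y (moved by WT replicates 1, 2 and 3 and C1483Y replicate 2) and 33 to 62 for RPF Torin1 (moved by each library but WT replicate 2). It gave 7 to 172 for mRNA C1483Y (WT replicates 1 and 3, C1483Y replicates 1 and 2) and 0 to 1 for mRNA Torin1 (each library but Torin1 replicate 1, without which the gene called was lower). TE gave 0 to 21 for C1483Y (WT replicate 1, C1483Y replicates 2 and 3), 2 to 3 for Torin1, and 0 to 39 for the direct comparison (Torin1 replicates 2 and 3, C1483Y replicates 1 and 2).

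Of lists past the threshold in camera, an estimated correlation left 0 of 6 for RPF C1483Y, 9 of 15 for RPF Torin1, 0 of 4 for mRNA C1483Y, 0 of 2 for each TE comparison with WT and 0 of 6 for the direct one. With fry, 13 passed for RPF C1483Y and 0 for TE C1483Y. The median TE change of ribosomal proteins in C1483Y, 0.34, became -2.05 with DESeq2 size factors, 0.56 without a filter, 0.44 with a replicate block by culture, and -0.13 (without WT replicate 2) to 0.58 with 1 library left out. Under Torin1 it ranged from -2.37 to -1.58. For other TOP mRNAs it was -2.75 with size factors in C1483Y (-0.45 with TMM) and -0.99 without a filter under Torin1, where it ranged from -1.63 to -1.21 with 1 library left out. Size factors rescale each library, which moved the median of all genes as well.

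Among named genes, Irs4 in mRNA under Torin1 went to -0.46 without Torin1 replicate 3 and to -0.43 without the near-identical libraries. Hif1a TE in C1483Y went to 6.59 without them, and Eef1a1 TE in C1483Y against Torin1 to -0.20 with size factors. Over all named genes and settings, RPF Torin1 kept the side of the threshold in 805 of 909 (3 of these not called and of the other sign), lost a call in 55 and gained in 49. RPF C1483Y kept the side in 640 of 659 (10 of the other sign), mRNA C1483Y in 390 of 451 (32), mRNA Torin1 in 177 of 193 (9), TE C1483Y in 330 of 359 (17), TE Torin1 in 281 of 300 (16) and the direct comparison in 444 of 507 (26). A fold of at least 1.5 changed no count.

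The 6 libraries of 2 groups make 10 splits, too few for a share under 0.1. For RPF C1483Y 1 split, the real one, gave as many genes (2060, highest other 0), and for RPF Torin1 1 split (83, highest other 0). For mRNA it was 2 splits in C1483Y (23, highest other 23) and 8 under Torin1 (1, highest other 3). For TE it was 10 splits in C1483Y (0, highest other 14), 2 under Torin1 (2, highest other 6), and 3 in the direct comparison (6, highest other 21). The 21 genes came from C1483Y replicates 1 and 3 set with Torin1 replicate 2, and the 14 from C1483Y replicates 1 and 3 set with WT replicate 3, which points to a structure of the samples.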

Other observations

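These values were chosen after they were seen. Histone genes went both ways in RPF labelled C1483Y, with 12 up and 18 down of 59 (13 and 21 adjusted over the list alone), from Hist1h4d (log2 -4.87) and Hist1h4h (-3.42) to Hist1h2be (3.06). Ckb stood at 2500 to 2710 CPM in RPF labelled C1483Y and at most 13.3 CPM in the other RPF libraries. Some genes that were abundant in RPF labelled C1483Y and at 0 or 1 read in WT libraries had reads in Torin1 RPF replicates 1, 2 and 3: Car2 had 0, 1 and 129, Coch 1, 1 and 40, and Uchl1 5, 1 and 119. Tmem38b (chromosome 4, 53825988 to 53862019) took 9.43%, 0.04% and 1.22% of gene counts in WT RPF replicates 1, 2 and 3, 11.7%, 0.29% and 37.02% in C1483Y, and 26.92%, 0.09% and 12.85% under Torin1.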
